A study of Homo sapiens with 4 samples.

How the data were processed

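Total RNA from Huh1 and Huh7 cells transfected with a negative control siRNA or an ODC1 siRNA was made into libraries with the Illumina TruSeq RNA kit, per the labels' protocols. CASAVA 1.8.2, TopHat2 2.0.9 and the genome build hg19 are named in the submitters' processing notes. The program that counted reads, the annotation release and the use of strand are not given in the sources used here, so reads of overlapping antisense genes may be mixed. The files hold RPKM values per RefSeq transcript that the authors computed and deposited, with no header. Per the labels, each of the 4 libraries is a different combination of line and siRNA, and no label gives a batch or a replicate number.

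Each library listed 18398 transcripts with 18382 different symbols, of which 16 stood on 2 rows, and 1543 transcripts were at 0 in all libraries. No mitochondrially encoded gene of the list fixed for them was present. RPKM values are scaled to library depth and transcript length, so a count model was not used. Relative depth was recovered from the ratios of values under 0.3 RPKM between libraries, and absolute depth from the value of 1 read and the length of the transcript in GENCODE release 29. Of the low values compared, between 43.6% and 49.5% stood in ratios of whole numbers (relative tolerance 1e-06), so the rest cannot be read as whole reads. Read counts were used for counting intervals, counting noise and the trend on counting variance. Those of ODC1 used 2062 bases, the length nearest the GENCODE one at which its 4 values were whole reads (tolerance 0.01 reads), and those of other genes the GENCODE length. Counting intervals have a confidence level of 95%, ODC1 intervals are exact Clopper-Pearson intervals of the share of reads, and all cover counting error only.

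Values were analysed as log2(RPKM + 1). Within a line, genes with at least 1 RPKM in either library were counted when they changed at least 2-fold, a rule of size with no p-value. Over both lines, limma 3.58.1 (R 4.3.3) was fitted with line and siRNA as terms and an intensity trend, to the 12039 genes with at least 1 RPKM in any library. The 1 residual degree of freedom is the difference in siRNA effect between the lines, and limma moderates the variance it gives with the trend over all genes, which counted as 7.42 further degrees of freedom. The standard error of a gene is therefore set mostly by other genes of like expression, and ODC1 passed although its log2 fold changes in the lines were -2.01 and -4.30. P-values therefore measure the spread between these libraries and not between independent cultures of a line. Adjustment followed Benjamini and Hochberg with a threshold of 0.05. The lines pair the control and ODC1 libraries, and the line term is the block for this pairing.

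Of the 31 gene lists written before the data were examined, 28 had at least 5 tested genes. For each, the median per line was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Over both lines, camera was run with a preset correlation of 0.01, then with an estimated correlation, and fry was run beside it. With the preset correlation, camera counts the genes of a list as nearly independent, so its p-values do not measure the spread between libraries. Camera with an estimated correlation and fry rest on the 1 residual degree of freedom, so they had little power to call any list. The markers of blood cells and of endothelium had 3 and 2 tested genes and were not tested as lists.

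Genes were named by a rule fixed before the data were examined. It took ODC1, KLF2 and PPARG, and in each line the 8 largest rises and the 8 largest falls among genes with at least 5 RPKM in the higher library. It also took up to 12 genes each way among those changed at least 2-fold alike in both lines, up to 4 members of each list with the largest mean change, and the 10 largest differences between the lines each way. Levels of sex-linked marker genes were left out. A few genes that the rule takes are not reported here.

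The fit was tested on data simulated for the comparison over both lines, with 200 genes changed among at least 11628 tested in each of 5 simulations. Each changed gene had at least 5 RPKM in some library and the same fold in both lines, and the dispersion was 0.005. The simulated siRNA effect did not differ between the lines, so the shares below do not cover genes whose effect differs. The fit recovered 85.1% of genes changed 1.5-fold, 98.3% of those changed 2-fold and 100% of those changed 4-fold. Unchanged genes made up 16.7% of its calls, above the nominal threshold. A trend on the variance that counting alone gives lowered this share to 6.19%, and it was added as an alternative after this result was seen. The other settings, written before the data were examined, were quantile normalization, upper quartile scaling, a pseudocount of 0.1, no filter, a filter at 5 RPKM, a 1.5-fold rule, limma without trend, no line term, and each library left out in turn.

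For words in 3' UTRs, the bases after the stop codon were taken from the GENCODE transcripts (GRCh38) matched to the RefSeq accessions, which gave 11422 genes with at least 50 bases besides ODC1. This annotation is of a later build than the one in the submitters' notes. Changes limited to 1.2 either way on the log2 scale were corrected for length, GC content and expression, and each 7-base word with at least 50 carriers was scored by the mean difference between carriers and other genes. On simulated changes with a planted word of the ODC1 mRNA and a shift of -0.2 in its carriers, all 10 planted words were found. The words reported below had smaller shifts, which this simulation did not cover. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.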

Results

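RNA sequencing was used to measure gene expression in Huh1 and Huh7, established human hepatocellular carcinoma cell lines, after transfection with a negative control siRNA or an siRNA against ODC1. ODC1 encodes ornithine decarboxylase, the rate-limiting enzyme of polyamine synthesis. Each of the 4 combinations of line and siRNA was represented by 1 library, so there was no replicate within a line. The deposited values were RPKM for 18398 RefSeq transcripts. The depth recovered from the steps between low values was 13384836 reads for Huh1 with control siRNA and 11227128 for Huh1 with ODC1 siRNA. It was 12197606 reads for Huh7 with control siRNA and 10215332 for Huh7 with ODC1 siRNA. On a transcript of 2 kb, 1 read was worth between 0.0374 and 0.0489 RPKM in these libraries. Log2 fold changes were taken on log2(RPKM + 1) and therefore understate the change of weakly expressed genes.

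The targeted transcript was examined first. ODC1 (NM_002539; chromosome 2, 10439968 to 10448504, minus strand, in the GRCh38 annotation) was lower with the ODC1 siRNA in both lines. In Huh1 it stood at 103 RPKM with control siRNA and 25.01 RPKM with ODC1 siRNA, so that 24.2% remained (95% interval 22.1% to 26.5%). In Huh7 it stood at 167 RPKM and 7.50 RPKM, so that 4.49% remained (95% interval 3.81% to 5.27%). At a length of 2062 bases, at which all 4 ODC1 values are whole reads, these exact binomial intervals rest on 2854 and 579 reads in Huh1 and on 4198 and 158 reads in Huh7, and cover counting error only. The direction in both lines is that of the labels.

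**Figure D1:**
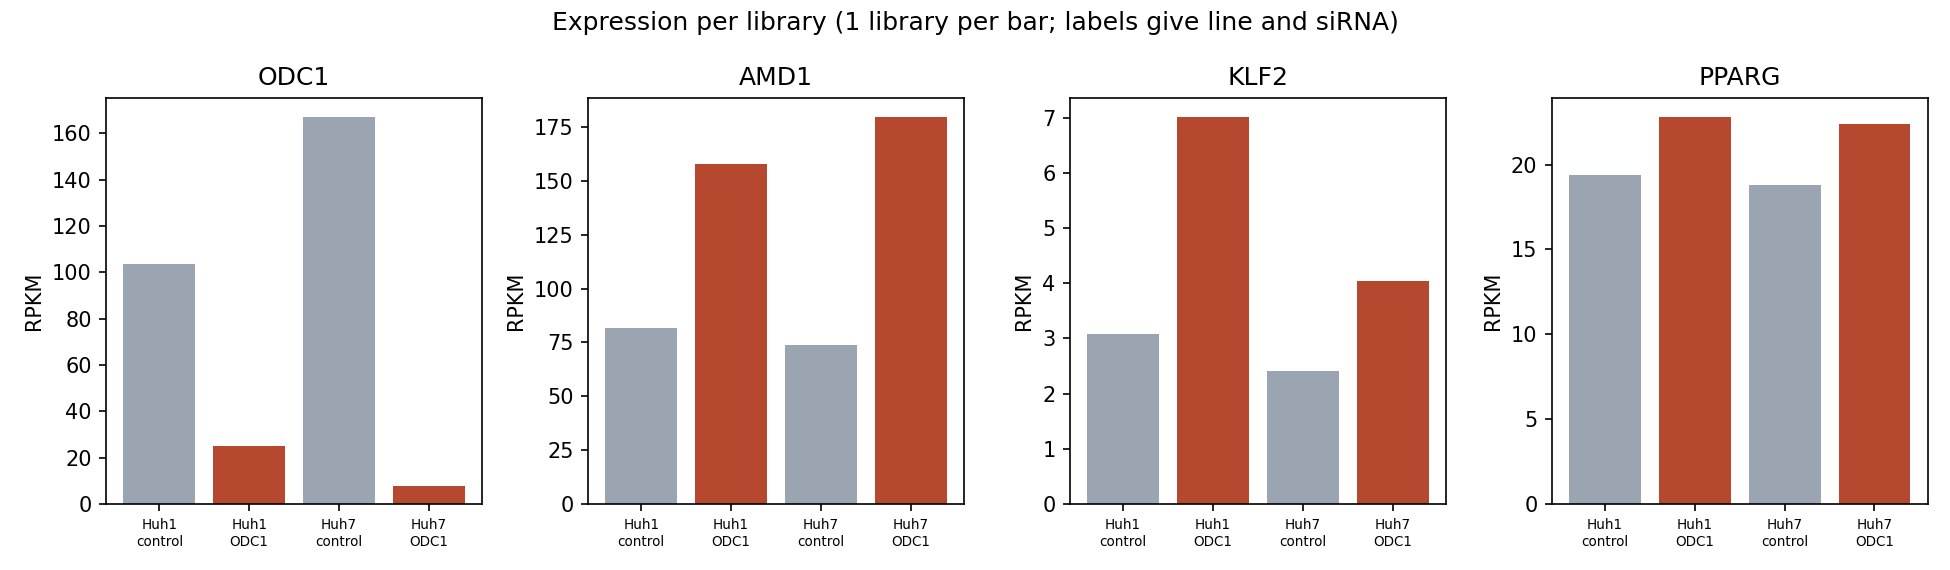
Expression in RPKM of ODC1, AMD1, KLF2 and PPARG in the 4 libraries, with 1 bar per library, grey for control siRNA and red for ODC1 siRNA. ODC1 goes from 103 to 25.01 RPKM in Huh1 and from 167 to 7.50 RPKM in Huh7, while AMD1 and KLF2 are higher with ODC1 siRNA in both lines.

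The first comparison asked which genes differed between ODC1 and control siRNA within Huh1. The largest rises by size were TPM4, a tropomyosin of the actin cytoskeleton (19.1 to 50.4 RPKM, log2 fold change 1.35), and CYP1B1, a cytochrome P450 induced by the aryl hydrocarbon receptor (13.5 to 34.8 RPKM, 1.30). ZNF616 (1.18), NTN4 (1.07), KLF2 (0.97), AMD1 (0.95) and PAGE1 (0.94) were also among them. After ODC1, the largest falls by size were OSGIN2 (41.6 to 18.4 RPKM, -1.14) and CDKN1A, which encodes the cell cycle inhibitor p21 (18.6 to 8.33 RPKM, -1.07). DYNLT3 (-0.97), the carbonic anhydrase gene CA2 (-0.95), the riboflavin kinase gene RFK (-0.93), AKR1B15 (-0.93) and S100A9 (-0.91) came next. AKR1B15 shares sequence with the far more abundant AKR1B10, so its value is uncertain. Of 10912 genes with at least 1 RPKM in either Huh1 library, 6 were at least 2-fold higher and 3 at least 2-fold lower. Counting noise alone gave a median of 0.5 and at most 4 such genes in 20 simulated pairs. These differences have no replicate check, and with a pseudocount of 0.1 the 9 genes became 45.

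The same question in Huh7 gave more genes. The largest rises by size were HABP4 (6.22 to 22.5 RPKM, log2 fold change 1.70), CYP1B1 (1.53), the EGF receptor ligand gene EREG (13.6 to 40.6 RPKM, 1.51) and the extracellular matrix gene TNC (1.97 to 7.19 RPKM, 1.46). TPM4 (1.40), PTX3 (1.38) and TUFT1 (1.31) were also among them. After ODC1, the largest falls by size were RFK (36.8 to 10.02 RPKM, -1.78), the MAP kinase phosphatase gene DUSP9 (107 to 39.4 RPKM, -1.42), CYGB (-1.38), REEP6 (-1.32) and the glycolytic aldolase gene ALDOC (51.9 to 20.3 RPKM, -1.31). FADS1, a fatty acid desaturase gene, was at -1.27 and GLUD1, the glutamate dehydrogenase gene, at -1.23. Of 11416 genes with at least 1 RPKM in either Huh7 library, 39 were at least 2-fold higher and 49 at least 2-fold lower. Counting noise alone gave a median of 1 and at most 4. With a pseudocount of 0.1 the 88 genes became 236. The design has no replicate with which to test the difference in number between the lines.

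The 2 lines shared no library, and their changes were then set side by side. The genes at least 2-fold higher in both lines included CYP1B1, TPM4 and ZNF616, and ODC1 and OSGIN2 were at least 2-fold lower in both. Independent lists would share 0.0194 genes among the higher and 0.0122 among the lower. No gene reached 2-fold in opposite directions. Across 12039 genes with at least 1 RPKM in any library, the log2 fold changes in Huh1 and Huh7 correlated with Pearson's r = 0.446 and Spearman's rho = 0.424. This correlation is across genes, which are not independent replicates. It was 0.439 without ODC1.

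**Figure D2:**
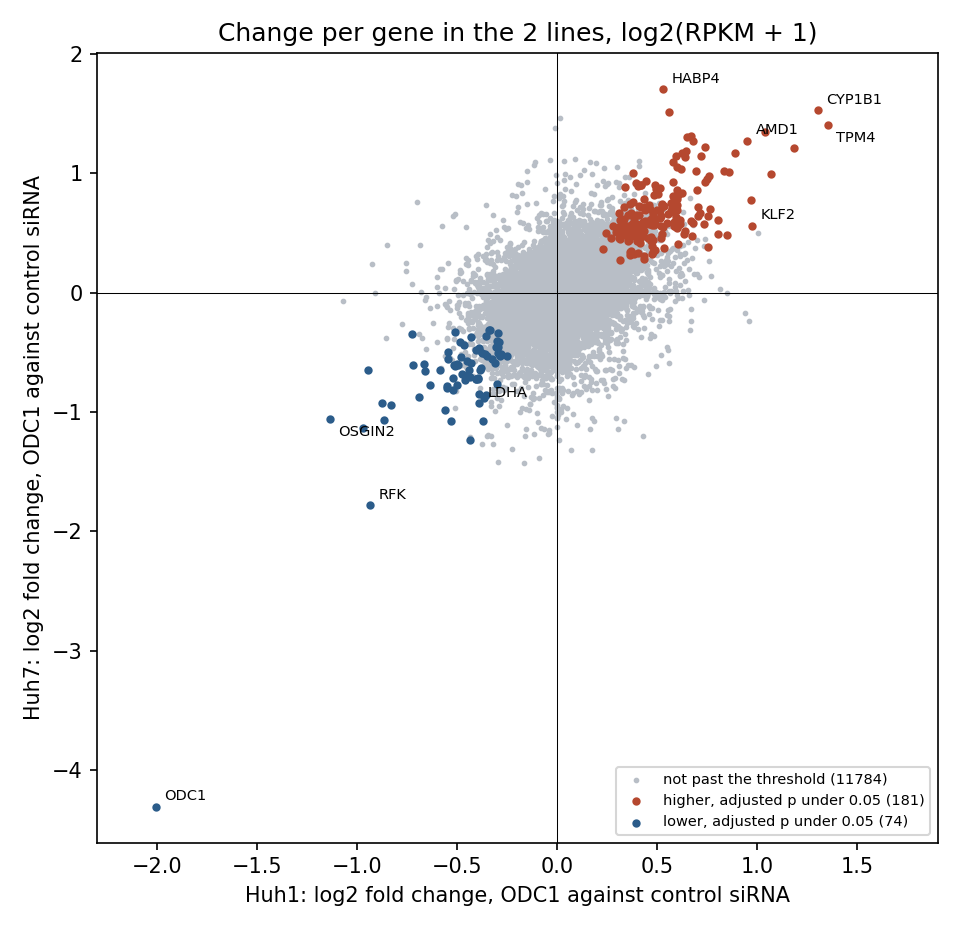
Log2 fold change on log2(RPKM + 1), ODC1 against control siRNA, in Huh1 (horizontal axis) and Huh7 (vertical axis), with 1 point per gene. Red points (181 genes) were higher and blue points (74 genes) lower past the threshold in the fit over both lines, and ODC1 lies lowest in both lines.

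The effect of ODC1 siRNA over both lines was tested next, with the lines as the repeat of the treatment. AMD1, the gene of S-adenosylmethionine decarboxylase, which supplies the aminopropyl groups of polyamine synthesis, rose in both lines (81.5 to 158 RPKM in Huh1 and 73.8 to 180 RPKM in Huh7). Its mean log2 fold change was 1.11 (SE 0.085, limma adjusted p = 0.00239). TPM4 rose by 1.38 (SE 0.066, adjusted p = 0.000179), CYP1B1 by 1.42 (adjusted p = 0.00239), ZNF616 by 1.197 (adjusted p = 0.00888) and NTN4 by 1.03 (adjusted p = 0.0078). OSGIN2 fell by 1.097 (SE 0.085, adjusted p = 0.00239), DYNLT3 by 1.05 (adjusted p = 0.00312), RFK by 1.36 (adjusted p = 0.0157), GLUD1 by 0.84 (adjusted p = 0.0372) and CA2 by 0.80 (adjusted p = 0.0183). Of the genes with large rises in Huh7, HABP4 rose by 1.12 (adjusted p = 0.0483), EREG by 1.03 (adjusted p = 0.0369) and TUFT1 by 0.99 (adjusted p = 0.0221), while TNC and PTX3 did not pass. ODC1 itself fell by 3.15 (SE 0.40, adjusted p = 0.0157).

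KLF2 and PPARG were examined because the study concerned these transcription factors and lipid metabolism. KLF2, a Krüppel-like factor, was at 3.08 and 7.01 RPKM in Huh1 and at 2.42 and 4.04 RPKM in Huh7 with control and ODC1 siRNA, and rose by 0.77 (SE 0.14, adjusted p = 0.0397). The call was kept with the trend on counting variance and lost with quantile normalization (0.75), upper quartile scaling (0.76), a pseudocount of 0.1 (0.94) and a filter at 5 RPKM (0.77), each of which called other genes. PPARG, a nuclear receptor of adipogenesis and lipid storage, was at 19.4 and 22.8 RPKM in Huh1 and at 18.8 and 22.4 RPKM in Huh7. Its log2 fold change of 0.23 (SE 0.085) did not pass the threshold (adjusted p = 0.192). CDKN1A also did not pass (adjusted p = 0.184).

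In all, limma called 181 genes higher and 74 lower among 12039. An unadjusted p under 0.05 was reached by 2286 genes, where 602 would be expected. The count depended on the settings and ranged from 0 to 330. The 19 genes called under each of 6 settings that gave calls included AMD1, TPM4, CYP1B1, ZNF616, NTN4, OSGIN2, DYNLT3 and MT1E, but not ODC1, KLF2 or RFK, and the other calls of the 255 were lost under at least 1 of these settings. These 19 genes are all the calls of upper quartile scaling, the strictest of the 6. Settings that called 0 genes were left out of this set, so none of the 19 passed under those. The 3' UTRs of OSGIN2, DYNLT3, RFK, CA2, GLUD1, LDHA, MSMO1, STARD4, AGPAT5, GPAM and DUSP9 contain the 7-base word ATATCAT, which also occurs in the ODC1 mRNA. So do those of LYVE1, VLDLR, COL3A1, GJA1, VNN1 and VGLL3, which were at 0.30, 0.23, 0.21, 0.10, 0.097 and 0.091 over both lines without passing. The 3' UTRs of UQCRC2 and ZMAT3, at -0.38 and -0.32 without passing, contain it too. Those of CYP1B1, TPM4, HABP4, TUFT1 and NOLC1 contain TCGGAGA. The 3' UTR of AMD1 contains neither.

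Gene lists fixed before the data were examined were then compared, 28 of them with at least 5 tested genes. Genes of cholesterol synthesis were lower together. All 25 were tested, 20 had a negative log2 fold change in Huh1 and 23 in Huh7, and the medians were -0.22 and -0.51. Of these, 7 fell and none rose past the threshold over all genes. Adjusted over the list alone, 16 fell and 1 rose. This rule, also used for lists below, is looser and makes no correction over the lists. In the same limma fit, 2286 of all 12039 genes had an unadjusted p under 0.05. Isopentenyl isomerase IDI1 fell by 0.62 (adjusted p = 0.0299), HSD17B7 by 0.62 (adjusted p = 0.0265, a call lost with the trend on counting variance) and the sterol oxidase gene MSMO1 by 0.57 (adjusted p = 0.0244). STARD4 was at -0.33 in Huh1 and -0.91 in Huh7 (adjusted p = 0.0612), and passed with the trend on counting variance. Of 24 genes with a searched 3' UTR, 3 contain ATATCAT and 1 TCGGAGA, and the other 20 had a median of -0.51 in Huh7. The list was lower in limma's camera test with a preset correlation (adjusted p = 8.78e-10), which counts its genes as nearly independent and does not measure the spread between libraries. The call was lost with camera's other setting (adjusted p = 0.731 with an estimated correlation) and by fry (adjusted p = 0.572).

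The list of fatty acid and triglyceride synthesis was also lower (21 genes, medians -0.20 in Huh1 and -0.33 in Huh7, camera adjusted p = 0.000185), but not with the correlation estimated (adjusted p = 0.731 with an estimated correlation). Single genes seldom passed the threshold, with 1 higher and 1 lower. Adjusted over the list alone, 1 was higher and 9 were lower. Its members with the largest changes were the desaturase genes FADS1 (-0.38 and -1.27, adjusted p = 0.0507), FADS2 (-0.28 and -0.90, adjusted p = 0.0525) and SCD (-0.20 and -0.83, adjusted p = 0.0717), and all 3 passed with the trend on counting variance. The list of KLF2, PPAR factors and PPAR targets had a median of 0.16 in Huh1, at percentile 99.9 of random lists matched on expression, and of -0.11 in Huh7, at percentile 4.59. It was not called (camera adjusted p = 0.922). Of its members with the largest changes besides KLF2, the fatty acid oxidation gene ACADM was at -0.11 in Huh1 and -0.72 in Huh7, CIDEC at 0.56 and 0.11, and PDK4 at 0.66 and 0.03, and none of the 3 passed the threshold. In glycerophospholipid synthesis, 27 genes were tested and none passed (camera adjusted p = 0.312), with 14 negative in Huh1 and 20 in Huh7. Adjusted over the list alone, 2 were higher and 2 lower. AGPAT5 was at -0.47 over both lines, GPAM at -0.45 and PTDSS2 at -0.45. CDS2 and LPCAT1, the latter chosen after its values were seen, passed with the trend on counting variance (0.53 and 0.42 over both lines).

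Genes of glycolysis and hypoxia were lower mainly in Huh7. The median of the 26 genes was -0.05 in Huh1 (percentile 3.19) and -0.52 in Huh7 (below each of the 10000 random lists), and 6 genes were at least 2-fold lower in Huh7 while none was in Huh1. The list was lower over both lines (camera adjusted p = 4.04e-08), with 2 genes lower past the threshold over all genes. This call too was lost with the correlation estimated (adjusted p = 0.731 with an estimated correlation) and by fry (adjusted p = 0.572). Adjusted over the list alone, 17 were lower and 2 higher. LDHA, the lactate dehydrogenase A gene, went from 547 to 417 RPKM in Huh1 and from 1396 to 735 RPKM in Huh7, and fell by 0.66 (adjusted p = 0.0265). PDK1, a hypoxia-induced kinase gene, was at -0.04 in Huh1 and -1.17 in Huh7 (adjusted p = 0.18), and PFKFB4, which passed with the trend on counting variance, was at -0.43 and -1.21 (adjusted p = 0.0545). The difference between the lines was not tested.

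Hepatocyte transcription factors were lower (16 genes, medians -0.09 and -0.36, camera adjusted p = 0.000185; adjusted p = 0.731 with an estimated correlation). None passed the threshold singly, though CEBPA did with the trend on counting variance. CEBPA was at -0.26 and -0.66 and NR5A2 at -0.30 and -0.89. Hepatocyte plasma proteins were lower as a list (medians -0.05 and -0.23, camera adjusted p = 0.00149; adjusted p = 0.731 with an estimated correlation). The albumin gene ALB fell by 0.32 (adjusted p = 0.0232) and the fibrinogen genes FGG and FGA by 0.38 and 0.36, but the transthyretin gene TTR rose by 0.47 (adjusted p = 0.0494, lost with the trend on counting variance). Heat shock proteins were lower (14 genes, medians -0.12 and -0.22, camera adjusted p = 4.82e-05; adjusted p = 0.731 with an estimated correlation). HSPA1A and HSPA1B passed the threshold, but they are near-identical copies whose reads cannot be divided with certainty. The lists of DNA replication (medians -0.05 and -0.15, camera adjusted p = 0.000336) and mitosis (medians -0.11 and -0.12, camera adjusted p = 0.00123) were lower, both calls being lost with the correlation estimated (each adjusted p = 0.731 with an estimated correlation). Among these cell cycle genes the cyclin E gene CCNE1 fell by 0.58 (adjusted p = 0.0449, lost with the trend on counting variance), and none of the mitosis genes passed, though MKI67 did with the trend on counting variance (-0.29 over both lines).

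Among the markers of other cell types, the fibroblast marker LUM rose by 0.39 (adjusted p = 0.0403), and its list was not called (5 genes, camera adjusted p = 0.0838). Of the NRF2 and glutathione genes, GCLM fell by 0.44 (adjusted p = 0.0265) and AKR1C3 by 0.33 (adjusted p = 0.0463, lost with the trend on counting variance).

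Metallothioneins, small metal-binding proteins, were higher in both lines (8 genes, medians 0.39 and 0.54, camera adjusted p = 4.82e-05; adjusted p = 0.731 with an estimated correlation). MT1E rose by 0.71 (adjusted p = 0.0118), MT2A by 0.67, MT1X by 0.65 and MT1F by 0.70, although MT1F was listed at 0 in Huh1 with control siRNA and the family members are close in sequence. With the trend on counting variance MT1E passed, and MT2A, MT1X and MT1F did not. Epithelial-mesenchymal and TGF-beta genes were higher (19 genes, medians 0.17 and 0.14, camera adjusted p = 0.00687; adjusted p = 0.731 with an estimated correlation), and CYR61, a matricellular protein gene, rose by 0.87 (adjusted p = 0.0174). Replication-dependent histones (10 genes, medians 0.15 and 0.41, camera adjusted p = 0.0189) and autophagy and lysosome genes (21 genes, medians 0.08 and 0.19, camera adjusted p = 0.0366) were higher too. The histone call was lost with no filter and the autophagy call with a filter at 5 RPKM, and neither held with the correlation estimated (each adjusted p = 0.731 with an estimated correlation). Histone copies are also similar in sequence, and most histone mRNAs lack a poly(A) tail.

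**Figure D3:**
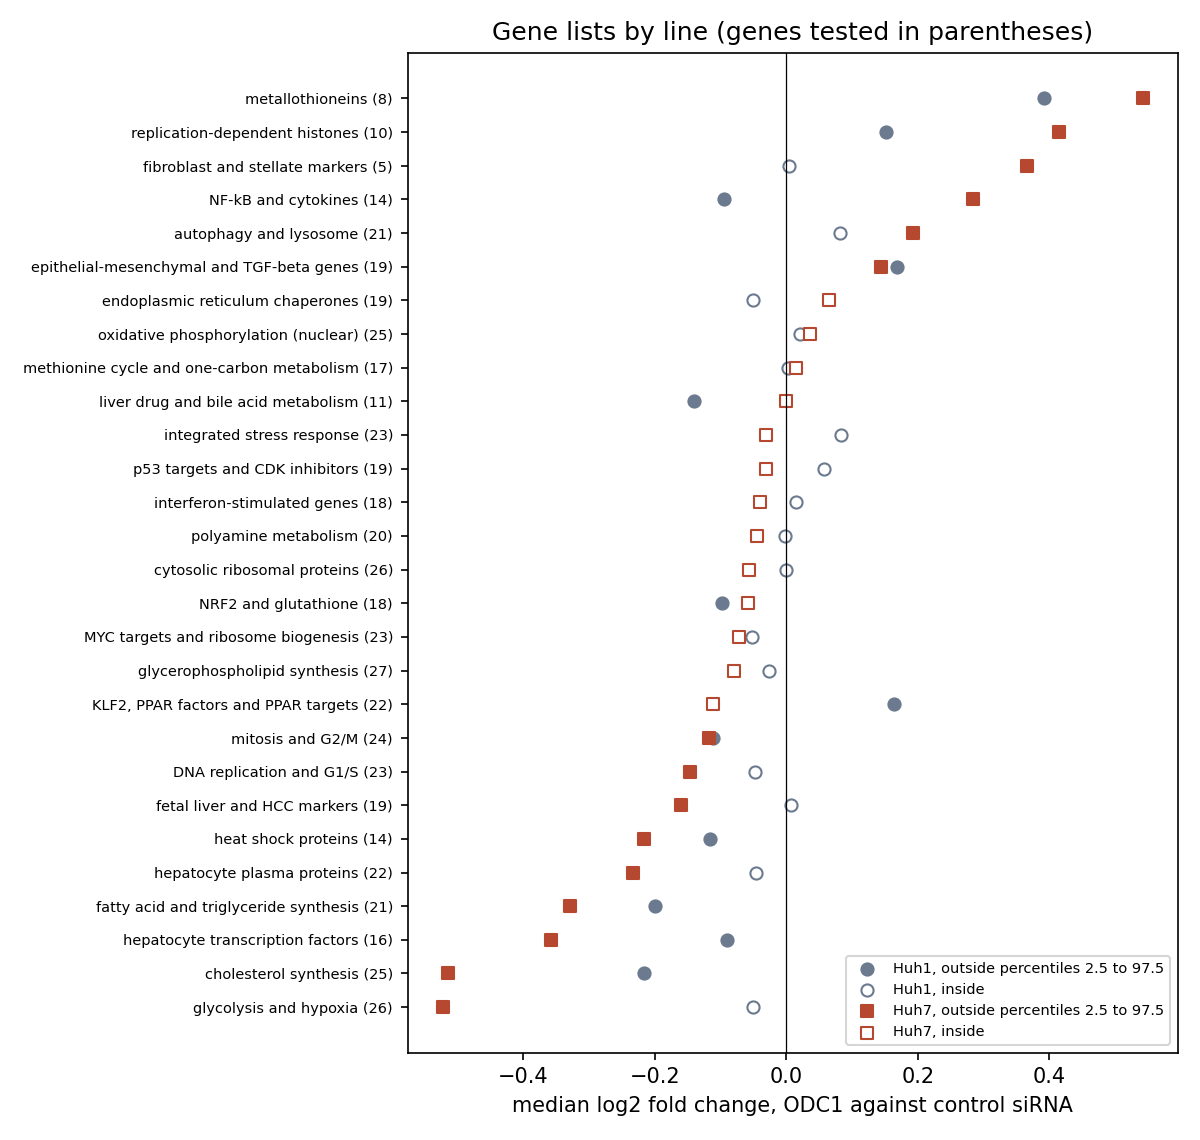
Median log2 fold change of the 28 gene lists in Huh1 (circles) and Huh7 (squares), ODC1 against control siRNA, filled where the median lies outside percentiles 2.5 to 97.5 of random lists matched on expression. Glycolysis and hypoxia (-0.52) and cholesterol synthesis (-0.51) are lowest in Huh7 and metallothioneins (0.54) highest.

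Across the lists, camera called 8 lower and 4 higher. By percentile among random lists, 8 of 28 lay outside 2.5 to 97.5 the same way in both lines, 5 low and 3 high. Of the lists camera called, some lay inside these bounds in Huh1. These were glycolysis and hypoxia (percentile 3.19), hepatocyte plasma proteins (6.2), DNA replication (6.65) and autophagy and lysosome (96.96). None of the 12 calls held with an estimated correlation (lowest adjusted p = 0.731 with an estimated correlation). Fry, which asks whether the genes of a list move on balance one way, called none (lowest adjusted p = 0.475). Both checks rest on the 1 residual degree of freedom and could hardly call any list. The correlations camera estimated rest on it too. They were 0.693 for cholesterol synthesis, 0.575 for glycolysis and hypoxia and 0.352 for fatty acid and triglyceride synthesis. The calls of these lists thus rest on the preset 0.01, which counts genes as nearly independent. Estimates were negative for metallothioneins, epithelial-mesenchymal and TGF-beta genes (-0.053) and autophagy and lysosome (-0.029). The other called lists had 0.022 to 0.289. The share of each loss due to low power was not tested. For metallothioneins, with an estimated correlation of -0.071, camera's unadjusted p went from 5.41e-06 to 0.133.

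The remaining comparison was between the lines. The carboxylesterase gene CES1 was at 1991 and 1962 RPKM in the Huh1 libraries and at 0.0817 and 0.146 RPKM in the Huh7 libraries (log2 difference -10.79, SE 0.075, limma adjusted p = 1.76e-11). AKR1B10 (-9.34), an aldo-keto reductase gene, GSTA1 (-9.00), CPLX2 (-7.59), AKR1B15 (-7.44), HPD (-7.35), the osteopontin gene SPP1 (-7.05), VNN1 (-6.90), LGALS4 (-6.82) and MSN (-6.82) were also higher in Huh1. The glutathione transferase gene GSTP1 was at 547 and 503 RPKM in Huh7 and at 0.078 and 0 RPKM in Huh1 (8.98, SE 0.083, adjusted p = 9.89e-11). UCHL1 (8.31), the chemokine gene CXCL5 (7.03), the connexin gene GJA1 (6.85), the collagen gene COL1A1 (6.75), the fetal growth factor gene IGF2 (6.73), EFEMP1 (6.54), FBLN1 (6.46), COCH (6.45) and VGLL3 (6.36) were higher in Huh7.

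By list, the NRF2 and glutathione genes were higher in Huh1, with 17 of 18 past the threshold and none the other way. All 11 tested genes of liver drug and bile acid metabolism, of 22 listed, were higher in Huh1. Mitosis genes were higher in Huh7 (23 of 24), as were all 8 metallothioneins. Of the 12 markers of fibroblasts and stellate cells, 5 were tested and all 5 were higher in Huh7. A gene that passes the filter through 1 line only has its direction fixed by the filter. COL1A1, COL1A2 and COL3A1 passed only through Huh7, with means of 0.095, 0.015 and 0.016 RPKM in Huh1. CYP3A5 and SULT2A1 of the liver drug list passed only through Huh1, with means of 0.89 and 0.42 RPKM in Huh7. In total limma called 5183 genes higher and 3708 lower in Huh7 among 12039, and 3193 differed at least 2-fold. The split between higher and lower moved with the scaling, to 4444 and 4264 with quantile normalization and to 4616 and 4147 with upper quartile scaling. The 2 libraries of a line differed in siRNA, and the fit removes the siRNA effect that the lines share. The spread behind this test is thus the difference in siRNA effect between the lines, moderated over all genes. Culture and line cannot be told apart with 1 culture per library.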

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

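The list and genes here were picked after their values were seen, because they moved in opposite directions in the 2 lines. The difference between the lines was not tested for any of them, since each line has 1 library per siRNA.

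The NF-kB and cytokine list had a median log2 fold change of -0.09 in Huh1, at percentile 1.46 of random lists, and of 0.28 in Huh7, at percentile 99.95, a difference of 0.38. It was the only list of 28 outside percentiles 2.5 to 97.5 in opposite directions. Of its 14 tested genes, 13 were higher in Huh7 past the threshold (median log2 difference between the lines 2.13). Some were therefore weak in Huh1, such as CCL2 at 0 RPKM, though CCL20 was at 22.1 and 12.7 RPKM there. The random lists were matched on mean expression over both lines and not within Huh1. Among 154 named genes, 3 lay outside their counting intervals in opposite directions with at least 3 reads in each library. The chemokine gene CCL20 was at -0.75 in Huh1 and 0.18 in Huh7, a difference of 0.94. The lipoprotein receptor gene VLDLR was at -0.20 in Huh1 and 0.67 in Huh7, a difference of 0.87. AKR1B10 was at -0.36 in Huh1 (5758 to 4489 RPKM) and 0.73 in Huh7 (5.07 to 9.09 RPKM), a difference of 1.09.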

How the results depend on the processing

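The trend on counting variance was chosen after seeing the data, and the other settings before. ODC1 stayed lower in both lines under each scaling and pseudocount. With a pseudocount of 0.1, the genes changed 2-fold numbered 45 in Huh1, 236 in Huh7 and 21 alike in both, and the correlation was 0.335. With a 1.5-fold rule, a looser one by construction, the counts were 150, 650 and 60. The correlation was 0.406 with no filter and 0.519 with a filter at 5 RPKM. Over both lines, the 255 genes called became 52 with quantile normalization, 19 with upper quartile scaling, 54 with a pseudocount of 0.1, 108 with a filter at 5 RPKM and 330 with a trend on counting variance, of which 216 were among the 255. Limma called 0 with no filter, where 2040 genes had an unadjusted p under 0.05, 0 without trend (1830 genes) and 0 without the line term, that is with no block for the pairing by line (22 genes). The cause of these shifts was not tested, except that without the line term the difference between the lines enters the spread. The lists called by camera went from 12 to 0 with an estimated correlation and to 0 by fry. Leaving out 1 library left no residual degree of freedom unless the line term was dropped too, and the fitted siRNA effect then followed the line difference, with correlations across genes of -0.924 and 0.928 without a Huh1 library and of 0.954 and -0.952 without a Huh7 library. Such fits called 0 genes over both lines for each library left out (between 1 and 9 genes at an unadjusted p under 0.05). Between the lines, fits with the siRNA term dropped called 4845 without the control library of Huh1, 4947 without its ODC1 library, and up to 7046 without a Huh7 library, against 8891.

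For 17 of the 41 called genes named over both lines, at least 1 of these fits turned the sign, by that construction. The ranges of their log2 effects were -3.16 to 1.56 for CA2, -0.19 to 2.94 for TPM4, -0.000207 to 2.07 for EREG, -1.27 to 0.11 for CCNE1, -0.26 to 1.63 for BTG2, -1.33 to 0.019 for LDHA and -0.78 to 1.73 for TTR. They were -1.12 to 0.48 for ALB, -0.048 to 1.71 for CYP1A1, -1.18 to 2.91 for CYR61, -2.20 to 1.33 for GCLM, -3.62 to 2.97 for AKR1C3 and -1.38 to 2.17 for LUM. For the metallothioneins they were -0.93 to 2.36 for MT1E, -2.06 to 3.45 for MT1F, -1.40 to 2.73 for MT2A and -0.77 to 2.08 for MT1X. Depth limits weakly expressed genes most, since 3 reads on a transcript of 2 kb are worth 0.112 to 0.147 RPKM.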

Other observations

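The tests of 7-base words, of GC content and length, and of the spread in each line had their outcomes written down before they were run. The test of scaling on the cholesterol and glycolysis lists, the tests over genes with none of the 10 leading words and the ratio of changes between the lines were chosen after the results were seen, as was the set of genes called under 6 settings.

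The 19 genes called under each of 6 settings also held TMEM93 (1.03), OGFR (0.93), the stress granule protein gene G3BP2 (0.92), MED11 (0.85), GANAB (0.83), PPP1R14B (0.69), the peroxiredoxin gene PRDX4 (0.69), the linker histone gene H1F0 (0.63), RDH11 (-0.90) and SERINC3 (-0.97), chosen after their values were seen. Of these, G3BP2 and MED11 contain TCGGAGA in the 3' UTR, RDH11 contains ATATCAT, and the others contain neither. Among the lower genes of the 19, OSGIN2, DYNLT3 and RDH11 thus contain ATATCAT and SERINC3 does not. Outside the lists already described, the immediate-early and stress genes PPP1R15A (0.64 in Huh1 and 1.19 in Huh7, limma adjusted p = 0.0163) and BTG2 (0.49 and 0.87, adjusted p = 0.0327) rose, as did CYP1A1, like CYP1B1 a target of the aryl hydrocarbon receptor (0.58 and 1.09, adjusted p = 0.021). The lists of integrated stress response (camera adjusted p = 0.312), p53 targets (0.633), interferon-stimulated genes (0.967), MYC targets and ribosome biogenesis (0.0748), cytosolic ribosomal proteins (0.277), nuclear oxidative phosphorylation (0.312), methionine cycle (0.675), endoplasmic reticulum chaperones (0.633), fetal liver markers (0.111), NRF2 and glutathione (0.0505, but called lower with upper quartile scaling and with no filter), NF-kB and cytokines (0.497), liver drug and bile acid metabolism (0.504), polyamine metabolism (0.497) and fibroblast markers (0.0838) were not called. In polyamine metabolism the spermidine acetyltransferase gene SAT1 was at -0.52 and -0.30 without passing the threshold (adjusted p = 0.0637).

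The first pattern is that genes changed alike in both lines. A candidate explanation for part of it is the seed region of each siRNA, which can lower transcripts with a matching site in the 3' UTR. Of 2382 words of the ODC1 mRNA, ATATCAT had the lowest carriers in Huh1, and in Huh7 it was the lowest of all 16133 words (percentile 0.0031). It was carried by 33 of 71 lower called genes (46.5%), against 10.1% of genes not called. This fell short of the 50% set beforehand for calling it the main source. The words were picked by Huh1 changes, which also enter the calls, so such differences in share are partly built in. The shares are also not corrected for length, GC content or expression. The percentiles in Huh7 do not depend on that choice. TCGGAGA, highest in Huh1, was at percentile 99.99 in Huh7 and was carried by 27 of 177 higher called genes (15.3%) against 1.54%, and GGAGAAA, which overlaps it, by 75 (42.4%) against 20.01%, as a seed of the control siRNA might give, so how much of each direction comes from seeds cannot be told apart from the response to ODC1 loss, with 1 siRNA of each kind and neither sequence given in the sources used here. Seeds acting directly at these words as the whole cause are argued against by the genes that lack the words. The correlation between the lines was 0.406 over the 10082 genes with neither ATATCAT nor TCGGAGA. It was 0.3601, close to the bound set, over the 5160 with none of the 10 words that led for either siRNA. Seed effects at other sites or passed on by a regulator would stay in these genes, so they remain open. A difference in culture between the control and ODC1 libraries, alike in both lines, also remains open. With 1 library per combination and no batch label it cannot be told apart from the siRNA. A GC or length bias is argued against by a correlation of 0.4545 once both trends were removed.

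The word ATATCAT occurs once in the ODC1 mRNA matched to NM_002539, at bases 1377 to 1383 of 2653, in the coding sequence in exon 9 of 12. In GRCh38 this is chromosome 2, 10442053 to 10442059, on the minus strand.

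The second pattern is that the lists of cholesterol synthesis and of glycolysis and hypoxia were lower, the latter mainly in Huh7, although neither call held with camera's correlation estimated (adjusted p = 0.731 with an estimated correlation) or by fry (adjusted p = 0.572). With GC content and length trends removed, the higher of the 2 list medians in Huh7 was still -0.5193, and under quantile normalization and upper quartile scaling it was at most -0.5242, which argues against both as the cause. Over members with neither ATATCAT nor TCGGAGA it was -0.4928, and over those with none of the 10 leading words -0.4031, which argues against siRNA seeds acting on the listed genes themselves. A response to the loss of ODC1, a seed effect on an upstream regulator, and a difference in medium, density or oxygen between the Huh7 cultures remain open and were not tested.

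The third pattern is that more genes changed 2-fold in Huh7 (88) than in Huh1 (9). Over 2852 genes of at least 20 RPKM in all libraries, the spread of log2 fold changes less counting variance was 0.145 in Huh1 and 0.224 in Huh7, a ratio of 1.546, which argues against counting noise. The stronger knockdown in Huh7 may contribute, and changes of called genes were larger there by a median ratio of 1.322, but the call favours equal changes and there is 1 knockdown per line, so it cannot be told apart from a property of the line or of the culture.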
